A study of Oryza sativa with 4 samples.

How the data were processed

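Total RNA from the developing leaf 9 of rice (Oryza sativa cv. Nipponbare, the japonica cultivar used for the reference genome) was measured after 7 h in elevated CO2. Per the labels' protocols, plants grew at 320 to 360 ppm CO2 and 0.5 g nitrogen per plant until leaf age 7.1 to 7.3, and 1000 ppm CO2 began at 6:00, the start of the day. Per the labels' protocols, 400 ng of RNA was labelled with the dye Cy3 and each sample was hybridised alone, so each array has 1 colour. The 4 samples form 1 group, numbered 1 to 4 in the labels and described there as independent experiments. Neither plants at ambient CO2 nor the later time point of 13.5 h were analysed here, so no comparison of CO2 levels was made.

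Per the file headers, the authors scanned an Agilent rice array of design 015241 and extracted spots with Feature Extraction 11.5.1.1. The deposited intensity of each spot, the processed signal, is background-subtracted and detrended within its array, per the file headers, and is not normalised between arrays. The deposited flags for other spot properties (well above background, positive and significant, saturated, outlier) are 0 or 1, per the file headers. The deposited value table holds a ratio, each processed signal over that array's 75th percentile on a linear scale, as comparison with the intensities showed: processed signal over value had medians of 4773, 4753, 3471 and 3540 in replicates 1 to 4, against 75th percentiles of 4770, 4750, 3470 and 3540. Its column medians were 0.44, 0.44, 0.44 and 0.43, and it is not centred per probe. The filter behind its 31717 rows is not given in the sources used here: 182 rows were well above background on none of the 4 arrays, and 2055 spots well above background on all 4 were outside it. A planned test against the table's baseline needed centring on other samples and was therefore left out.

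Each log2 processed signal was expressed relative to the 75th percentile of its array, so all levels below are log2 values on that scale. Control spots and spots flagged as outliers (117, 57, 54 and 47 on the 4 arrays) were left out, and spots of 1 probe were averaged. Each array held 43734 non-control spots for 42477 probes, and no spot was saturated. A probe counted as detected when well above background on all 4 arrays. Gene names are the descriptions printed in the array files, which can be old; the reference table given did not carry these locus identifiers, so no coordinates are printed. Probe names gave a locus for 41908 probes and 29690 loci. Locus numbers follow the order of genes along each chromosome, and that order alone was used for neighbourhood.

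Replicates 1 and 2 lay on slide 1 and were scanned together. Replicates 3 and 4 lay on slides 2 and 3 and were scanned together in a second session, so scan session was treated as a batch of 2 arrays each.

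Genes differing between replicates were found with limma 3.58.1 in R 4.3.3, by a moderated F on the array term in a model with probe and array, over 6421 loci with at least 2 detected probes (the first 2 by name), with Benjamini-Hochberg adjustment at 0.05. The residual of this test is the disagreement of the probes of a gene, so its p-values speak of these 4 samples and cannot separate plants from labelling reactions. In 3044 of the 6421 pairs the probes shared a stretch of 15 bases or more, so they are not independent readings. For each of 24 gene lists, the SD over replicates of the list's mean deviation was ranked among 10000 random lists matched on level in 20 bins, for lists with at least 5 detected genes. The share of each list detected was compared with all other loci by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over lists; genes are not independent replicates in either. Lists were matched by keyword in the descriptions, and some keywords caught other proteins: 361 of the 477 cell cycle loci are cyclin-like F-box proteins, 19 of the 54 sucrose loci are described by pectin methylesterase inhibition, 66 of the 122 heat shock loci are DnaJ-type proteins, 5 of the 22 photorespiration loci are phosphoglycerate kinases, and 3 of the 29 jasmonate loci are potassium channels.

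The lists, tests and naming rule were fixed before the data were examined. The rule named the written-out loci of each list (at most 4 each), the 20 differing genes with the largest range whose probes had the same highest and lowest replicate, and the 3 members of widest range in each list above the 95th percentile. The first 2 probes of a gene were averaged. The settings varied by that plan were normexp background correction with an offset of 50, quantile and median normalization, cyclic loess for the lists, other filters on dim or saturated probes, the value table, other probe pairs, scan as a term, other matching of random lists, other detection calls, and leaving out each replicate. Further settings were chosen after seeing the data: probe pairs without shared sequence, cyclic loess for the single genes, lists without mismatched members, lists and spread within scans, removal of a GC trend (lowess span 0.3), and leaving out loci low in 1 replicate.

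On simulated data for the 6421 genes, the test recovered 76% of planted 1.5-fold, 90% of 2-fold, 100% of 4-fold and 98% of 8-fold changes in 1 replicate, with 9 false calls beside 200 planted genes and 0 with none planted. The simulation drew independent errors for the probes of a pair, which probes that share sequence need not have. Of 20 simulated lists of 30 genes with no shift, 1 passed the 95th percentile, and 20 of 20 with a shift of 0.5 did. These lists were random genes with independent errors of equal SD, so the rate without a shift was set by construction. They do not show how often lists of genes that vary together would pass. The number of arrays, 4, limits the precision of every value.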

Results

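Gene expression was measured in the developing leaf 9 of rice after 7 h at 1000 ppm CO2, in 4 replicate samples, 1 array each. The samples form a single group, so the account covers which transcripts were present, how far the replicates lay apart, and which genes and gene groups differed between them. It holds no value for the response to CO2. The 75th percentile of processed signal was 4770, 4750, 3470 and 3540 in replicates 1 to 4.

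Transcripts of photosynthesis, ribosomes and chromatin were detected almost completely in this tissue, and those of seed and pollen rarely. All 44 photosystem and light-harvesting loci, all 46 core histone loci, all 22 photorespiration loci and 150 of 151 cytosolic ribosomal protein loci were detected, as were 47 of 48 plastid ribosomal protein loci. By contrast, 8 of 38 seed storage loci, 3 of 25 pollen and anther loci and 6 of 16 root and vascular loci were detected. Over the array, 22169 of 29690 loci (74.7%) had a probe well above background on all 4 arrays, and 32384 of 42477 probes did. Against all other loci, 11 of the 24 lists differed by Fisher's exact test at an adjusted p of 0.05. The share was higher for photosystems (adjusted p = 2.26e-05) and lower for jasmonate and wound response (13 of 29 loci, adjusted p = 0.0027) and for root and vascular loci (adjusted p = 0.00548). It was also higher for the cell cycle list (384 of 477 loci, and 108 of 114 with the F-box proteins and other mismatched members left out, adjusted p = 1.73e-07) and lower for cell wall genes (50 of 83). All 12 Calvin cycle loci were detected, at an adjusted p of 0.0837, and 101 of 122 heat shock loci, at 0.0745. The lists that did not differ included all 9 chlorophyll synthesis loci, 16 of 18 for starch, 37 of 54 for sucrose, 8 of 12 for trehalose 6-phosphate and 31 of 40 for nitrogen. They also included 10 of 12 clock and flowering loci, 3 of 3 stomatal, 27 of 34 leaf patterning, 22 of 30 cytokinin and auxin, 65 of 88 drought and 5 of 8 aquaporin loci. With either looser detection call, 7 lists differed instead of 11. The calls lost were those of jasmonate (adjusted p = 0.0558 by the positive-and-significant call and 0.262 when any array sufficed), root and vascular (0.603 and 0.296), cell cycle (0.0558 and 0.131) and photorespiration (0.0558 and 0.0704). The root and vascular call was also lost without replicate 4 (adjusted p = 0.0753).

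Levels of the written-out loci are log2 values relative to the array's 75th percentile, as mean ± SD over n = 4 replicates. The genes for the small subunit of Rubisco, the enzyme that fixes CO2, stood at 0.79 ± 0.73 for Os12g0274700 and 0.95 ± 0.91 for Os12g0291100. Os12g0292400 stood at -0.77 ± 0.66 and Os12g0291400 at -4.75 ± 0.87. These latter levels rested on 1 detected probe each, so their difference from the other loci may lie in the probe. Protochlorophyllide reductase A (Os04g0678700), which makes chlorophyllide in the light, stood at 4.91 ± 0.51. The magnesium chelatase subunits chlI (Os03g0563300) and chlD (Os03g0811100) stood at 1.47 ± 0.25 and 0.54 ± 0.23. Of the enzymes that supply ADP-glucose for starch, the large subunit Os05g0580000 stood at 3.65 ± 0.13, the large subunits Os03g0735000 and Os01g0633100 at -1.72 ± 0.10 and -2.76 ± 0.23, and the small subunit Os08g0345800 at 1.72 ± 0.11. Sucrose synthase 1 (Os06g0194900) stood at 2.96 ± 0.04 and sucrose synthase 2 (Os03g0401300) at 4.08 ± 0.14. The sucrose-phosphate synthase locus Os01g0919400, with 1 probe, was not well above background on any array. Chloroplast glutamine synthetase (Os04g0659100) stood at 0.60 ± 0.07, and the nitrate reductases Os02g0770800 and Os08g0468100 at -3.99 ± 0.65 and -3.02 ± 0.27. Of the clock loci, the Myb gene Os08g0157600 stood at 0.51 ± 0.23 and the pseudo-response regulator Os03g0284100 at -0.44 ± 0.08. The bHLH gene Os11g0523700 and the ICE1 gene Os01g0928000, both on the stomatal list, stood at 2.53 ± 0.16 and 0.66 ± 0.15.

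The median SD between the 4 arrays was 0.17 log2 over detected probes, and 493 probes had an SD above 1. For the 163 probes with several spots, the median SD between spots within an array was 0.07 to 0.09, and that of single spots between arrays 0.29. Pairs from 1 scan had a median SD of 0.08 (replicates 1 and 2) and 0.12 (replicates 3 and 4), which cannot be set against an SD over 4 arrays. The median absolute difference was 0.12 and 0.17 in these pairs. Across scans it ranged from 0.16 (replicates 2 and 3) to 0.25 (replicates 2 and 4), so arrays of 1 scan were not always closer. The root mean square difference was smallest between replicates 1 and 2 (0.38) and largest between 1 and 4 (0.55), so no pair of arrays held the same values.

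The 20 genes of widest range whose probes had the same extremes included 3 acid phosphatases, 4 DUF1210 proteins of unknown function and 1 beta-expansin. Of 6421 loci tested with limma, 3600 (56.1%) differed between replicates, 436 of them by more than 2-fold and 100 by more than 4-fold. Pairs of probes that share sequence gave most of these calls. Of pairs that share no 15 bases, 1062 of 3377 (31.4%) differed when fitted alone. With scan session as a term 2322 loci differed, and without replicate 4, 1486. Among the loci past 2-fold whose probes had the same extremes, 272 of 366 were lowest in replicate 4.

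The widest range was that of Os03g0342100, a hypothetical protein, at -0.71 in replicate 4 and -7.85 in replicate 2 (adjusted p = 0.000376). A peroxidase (Os03g0339300) ranged 47.4-fold, from -2.66 in replicate 3 to -8.23 in replicate 2, with 3 of its 11 probes detected. Its lowest level was dim, as were those of Os03g0342100 (-7.85), Os05g0189300 (-8.20) and Os10g0555900 (-8.13) in replicate 2. Fold ranges that reach such levels depend on the background subtraction and are less certain. Of the class B acid phosphatases, Os05g0189300 was lowest in replicate 2 and ranged 40.6-fold, while Os05g0190500 and Os01g0191200 were lowest in replicate 4, with ranges of 4.64 and 4.20 log2. The neighbouring DUF1210 genes Os10g0150400, Os10g0150600, Os10g0150700 and Os10g0150800 were all highest in replicate 3 and lowest in replicate 4, with ranges of 11.2-fold to 38.5-fold. A beta-expansin (Os10g0555900), of a family that loosens cell walls, ranged 16.6-fold, and a glycine-rich cell wall protein (Os10g0450800) 12.5-fold. Also highest in replicate 3 were a 2OG-Fe(II) oxygenase (Os08g0417000), a plastocyanin-like protein (Os06g0218600), a harpin-induced protein (Os02g0538700), a DUF588 protein (Os06g0656300) and a cytochrome P450 (Os03g0140100), with ranges of 10.7-fold to 15.1-fold. The hypothetical protein Os02g0255700 was lowest in replicate 4, with a range of 13.3-fold. Lowest in replicate 1 were the VPS28 gene Os01g0781000 (4.12 log2), Os04g0329800 (18.7-fold) and Os04g0166000 (10.5-fold). Without replicate 1 the range of Os01g0781000 was 0.21 log2 and it no longer differed, and with no detection filter neither did Os02g0538700. The probes of Os10g0150600 and Os02g0255700 share no 15 bases, and those of the other 18 of these 20 genes do.

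**Figure D1:**
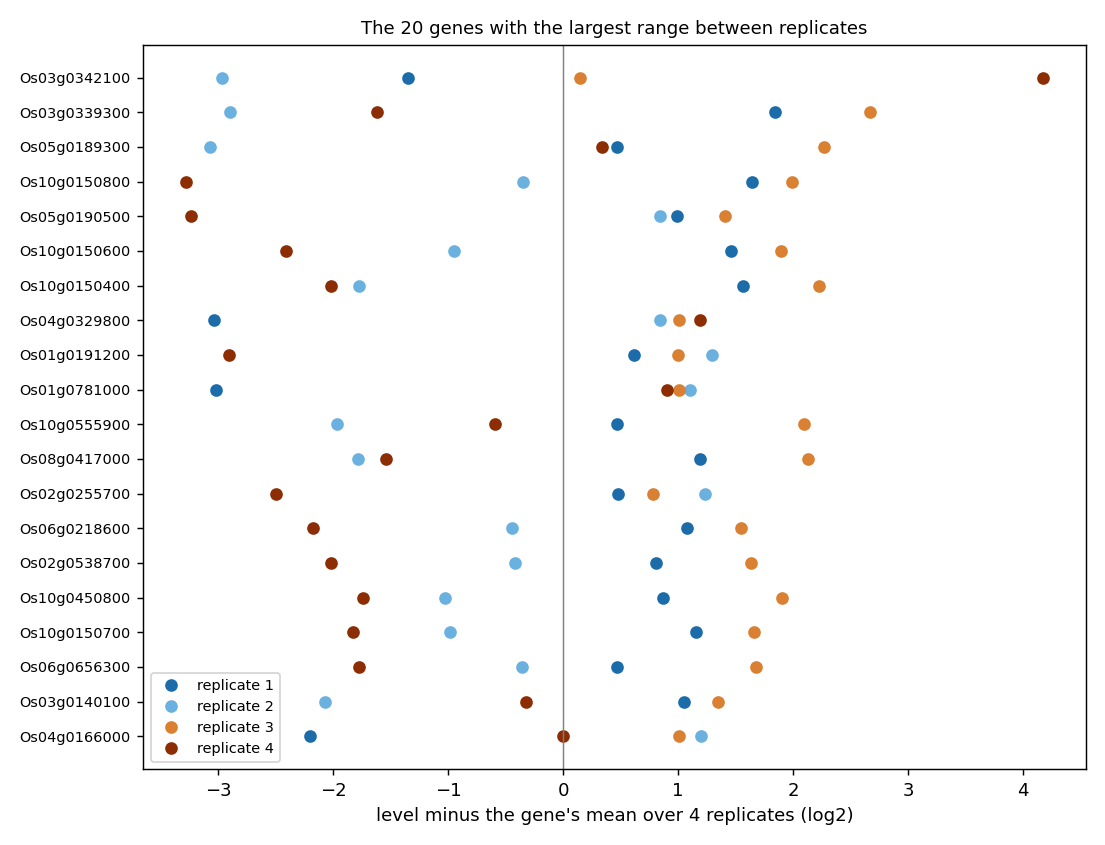
The 20 differing genes with the largest range between replicates, each as its log2 level minus its own mean over the 4 replicates (x axis), with 1 point per replicate. Os03g0342100 is highest in replicate 4, and the 4 DUF1210 genes of the Os10g0150400 to Os10g0150800 series are lowest there.

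The lists of photosynthesis genes had their lowest mean in replicate 4. The mean deviation of the 12 Calvin cycle genes was -0.81 log2 in replicate 4, 0.42 in replicate 3, 0.39 in replicate 2 and 0.00 in replicate 1. For the 44 photosystem and light-harvesting genes it was -0.53 in replicate 4 and 0.31 in replicates 2 and 3, and 41 of the 44 were lowest in replicate 4. Of the 12 Calvin cycle genes, 8 were lowest in replicate 4, 2 in replicate 1 and 2 in replicate 3. Of the 24 photosystem genes tested 23 differed, also when adjusted over the list alone, and so did 7 of 8 for the Calvin cycle. Within scan sessions, replicate 4 lay at -0.62 for the Calvin cycle and -0.42 for the photosystem list. Phosphoribulokinase (Os02g0698000), which regenerates the CO2 acceptor of the cycle, stood at -5.34 in replicate 4 and -2.17 in replicate 2 (adjusted p = 2.85e-05). Sedoheptulose bisphosphatase (Os04g0234600) ranged 4.57-fold, chloroplast fructose bisphosphatase (Os03g0267300) 3.91-fold and chlorophyll a-b binding protein 2 (Os01g0720500) 3.88-fold. The photosystem I subunits V (Os09g0481200) and psaK (Os07g0148900) ranged 3.60-fold and 3.00-fold. The 9 chlorophyll synthesis genes lay at -0.30 in replicate 4 and 0.25 in replicate 2, and 7 of the 9 were lowest in replicate 4. The 47 plastid ribosomal protein genes lay between -0.11 in replicate 1 and 0.13 in replicate 3, among them L18 (Os03g0828100, 1.98-fold). Under quantile and cyclic loess normalization replicate 4 was the lowest for this list (-0.13 and -0.16), and under median normalization its spread was at the 84.55th percentile. The Calvin cycle, photosystem and chlorophyll lists were lowest in replicate 4 under all 4 other scalings.

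Cytosolic ribosomal protein genes were highest in replicate 4, where the photosynthesis lists were lowest. Their mean deviation over 150 genes was 0.30 in replicate 4, 0.09 in replicate 3, -0.18 in replicate 2 and -0.20 in replicate 1, and 145 of the 150 were highest in replicate 4. Replicate 4 was the highest under all 4 other scalings, at 0.15 under quantile and cyclic loess normalization. These deviations divided by scan session: within sessions the SD of the list mean was 0.11 instead of 0.24, with replicate 4 at 0.10, replicate 3 at -0.10 and replicates 1 and 2 at -0.01 and 0.01, still at the 100th percentile. Of 60 tested, 58 differed, and 60 when adjusted over the list alone. L44 (Os07g0523300) ranged 1.76-fold, with an adjusted p of 0.0427, or 0.0567 among pairs that share no 15 bases, and S9 (Os03g0379500) stood at -2.42 in replicate 1 against 0.01 to 0.36 in the others. The 46 core histone genes lay at -0.14 in replicate 1 and 0.18 in replicate 4, at the 95.95th percentile of random lists. They were at the 78.4th within scan sessions, the 38.2nd under quantile normalization, the 66.3rd under cyclic loess, the 85.7th with brighter probes alone and the 94.0th with lists matched on probe number. They were at the 97.0th to 99.3rd with 1 replicate left out and at the 99.6th without the loci low in 1 replicate.

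The 13 jasmonate and wound genes lay at -0.55 in replicate 1 and 0.32 in replicate 3. One member, a Bowman-Birk proteinase inhibitor (Os01g0127600), stood at -7.59 in replicate 1 against -1.29 to -1.09 in the others. Without it the other 12 genes lay at -0.20, -0.13, 0.21 and 0.11 in replicates 1 to 4. Replicate 1 was then little below replicate 2, and the values divided by scan session. The list was at the 89.15th percentile without replicate 1, the 93.9th with no detection filter and the 91.2nd with brighter probes alone. Its highest replicate was 4 under median and quantile normalization. The potassium channel SKOR (Os04g0445000), matched by a keyword and not a wound gene by its description, ranged 3.76-fold. The 50 cell wall genes lay at -0.16 in replicate 4 and 0.17 in replicate 3, with a beta-expansin (Os02g0658800) 15.5-fold between extremes. Replicate 2 was the lowest for cell wall genes under median normalization (-0.10) and without Os02g0658800, the member low in replicate 4 alone (-0.13, against -0.10 in replicate 4), and with brighter probes alone the list was at the 73.55th percentile. The 27 leaf patterning genes lay at -0.18 in replicate 2 and 0.11 in replicate 1, among them Homeobox 20 (Os03g0727000, 4.66-fold); under median normalization replicate 4 was the highest. Drooping leaf (Os03g0215200), which shapes the rice midrib, stood at 1.32 ± 0.53 (SD, n = 4) and its probes disagreed (adjusted p = 0.378). The 101 heat shock genes, from a list in which 66 of 122 loci are DnaJ-type proteins, lay between -0.11 in replicate 1 and 0.10 in replicate 3 (replicate 4 was the highest under median normalization), with heat shock protein 26 (Os03g0245800) ranging 5.81-fold. Of markers of another tissue, the 8 detected seed storage genes lay at 0.42 in replicate 1 and -0.37 in replicate 2, led by an oleosin (Os06g0473800, 11.4-fold). The seed list was at the 29.8th percentile with no detection filter and the 82.3rd in the value table. Without replicate 1 the seed list was at the 76.2nd percentile (94.4th without replicate 2) and the heat shock list at the 75.8th, and without replicate 2 the leaf patterning list was at the 55.0th.

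In all, 11 of the 22 lists with at least 5 detected genes lay above the 95th percentile, and 10 of them had an adjusted share under 0.05, core histones being at 0.0812. Without the loci low in 1 replicate this share was 0.0117 for core histones and 0.054 for jasmonate, and with the GC trend removed it was 0.0552 for leaf patterning. The others were photorespiration (59.7th percentile), starch (59.6th), sucrose (94.7th), trehalose 6-phosphate (22.7th), nitrogen (48.1st), cell cycle (57.0th), clock and flowering (48.5th), cytokinin and auxin (60.4th), drought (1.26th), aquaporins (52.5th) and root and vascular markers (34.4th). The cell cycle list passed under normexp, quantile and median normalization, the sucrose list under 5 other settings, the root list under 2 and the nitrogen list with no detection filter. Within scan sessions 10 lists passed. Stomatal and pollen lists had 3 detected genes each and were not ranked.

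**Figure D2:**
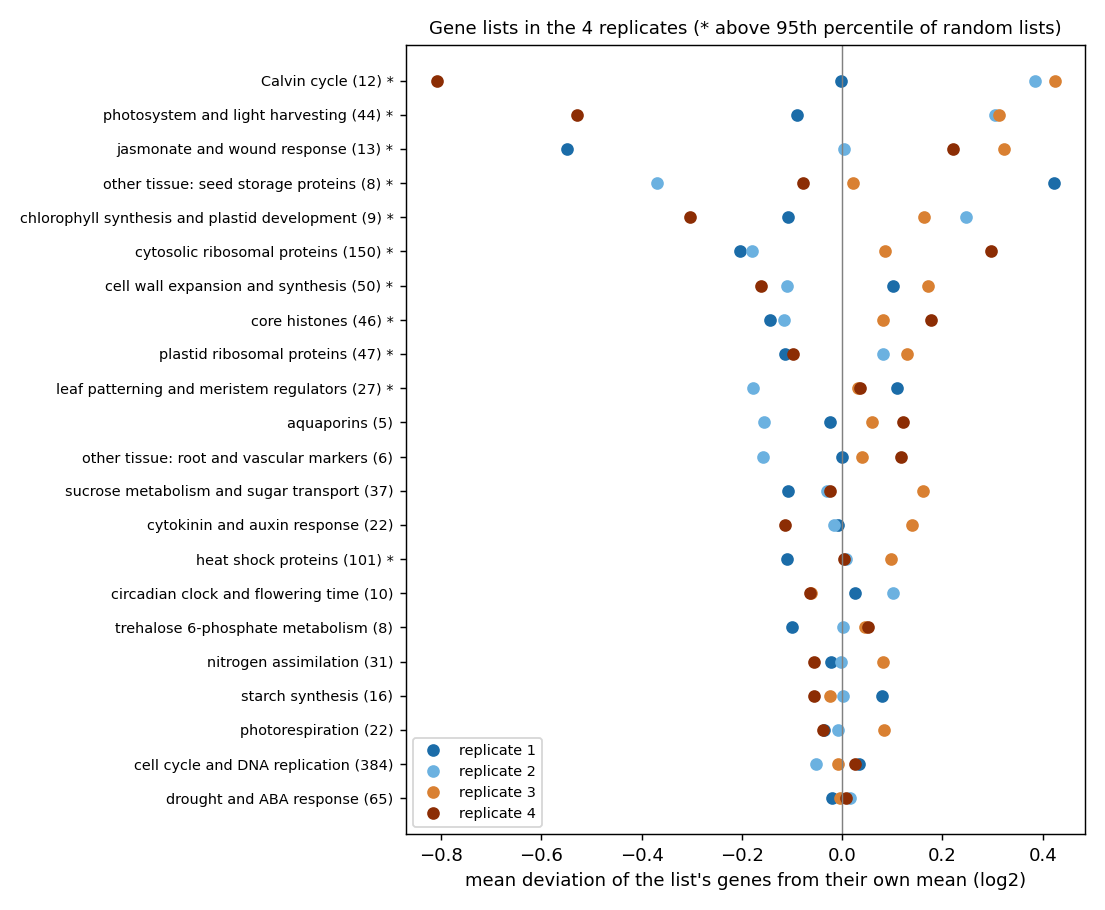
Mean deviation of each list's detected genes from their own mean over the 4 replicates (log2, x axis), with 1 point per replicate and the number of genes in brackets. Lists with a star lay above the 95th percentile of 10000 random lists; the Calvin cycle list spans -0.81 in replicate 4 to 0.42 in replicate 3.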

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

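Of the tests in this part, those of labelling, of the placing of loci and of the scan, and the spread for the jasmonate list, were chosen after the result was seen. Of 107 sets of 4 replicate values, 9 had 1 replicate far from the other 3, replicate 4 in 4 sets and replicate 1 in 5; chance gives about 1 in 20 for sets not picked for their spread, but 8 of the 9 are genes named for a wide range, so that rate does not hold for them. Replicate 4 stood apart for SL-TPS/P (Os05g0518600) at -5.71, against -4.66 to -4.54 in the others. It did so for the acid phosphatases Os05g0190500 at -4.45 and Os01g0191200 at -4.40, and for the beta-expansin Os02g0658800 at -6.03. Replicate 1 stood apart for Os04g0329800 at -6.80, VPS28 (Os01g0781000) at -5.12, histone H4 (Os07g0549900) at 3.73, ribosomal protein S9 (Os03g0379500) at -2.42 and the Bowman-Birk inhibitor Os01g0127600 at -7.59. Outside the gene probes, 99 of 340 probes for microRNA precursors were detected, against 1 of 24 random or artificial sequences (Fisher's exact test, adjusted p = 0.015). For mature microRNAs it was 36 of 170 (adjusted p = 0.0522). Of the 24 probes of genomic sequence 4 were detected, and the precursors were not tested against these.

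Loci far lower in replicate 1 alone neighboured each other more often than chance gives, although 34 of the 83 stood alone, with no other within 10 loci. At least 8-fold lower in 1 replicate, with the others within 2-fold of each other, were 102 probes in replicate 1, 1 in replicate 2, 0 in replicate 3 and 47 in replicate 4. Of these, 77 of the 102 and 27 of the 47 were not above background in that replicate, so the size of their difference was not measured. At least 8-fold higher were 9, 0, 2 and 0 probes. Probes had to be well above background in the other replicates, so a gain from an undetected level could not be counted. The 83 loci of replicate 1 made 18 neighbouring pairs with different descriptions, against at most 5 in 10000 random draws, so chance placing is argued against. Replicate 4 made 1. Only pairs with identical descriptions were left out, so related neighbours such as Os01g0781100 (rust resistance-like) and Os01g0781200 (Rp1-like) still counted. Pairs within a run are not separate events. The spots were not close together on the array (46.6th percentile of random draws), which argues against a local defect. Other probes of like level were not lower (median difference 0.0447 log2), so the loss was not shared by probes of like level. Levels were scaled within each array, which removes a weak labelling of the whole array. The median difference therefore cannot test weak labelling. Before scaling, the 75th percentile of replicate 1 was 4770, against 4750, 3470 and 3540 in replicates 2 to 4. Its median signal was 697, against 675, 507 and 478. These values argue against a weak labelling of replicate 1 as a whole. Flanking loci also differed by 2-fold or more beyond chance (8 of 111, 6 lower and 2 higher, against 0.976% elsewhere, 99.98th percentile), which is consistent with plants of replicate 1 carrying another sequence in these regions as a hypothesis; a shared change of expression in the regions was not tested and stays open.

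Calvin cycle and photosystem genes were lowest in replicate 4. Replicate 3, of the same scan, lay at 0.42 for the Calvin cycle. Deviations are from the mean of all 4 replicates, which replicate 4 lowers, so the sign of this value alone says little. Replicate 3 was not below replicates 1 and 2 of the other scan (-0.001 and 0.39), which argues against the scan. Removing each array's trend with probe GC left replicate 4 at -0.82, and under cyclic loess, which removes trends with signal level, both lists stayed at the 100th percentile. Replicate 4 was the only array on slide 3, so an effect of the slide cannot be told apart from the sample. No biological explanation was tested, since the design has 1 group. Leaf stage, slide and labelling of single samples stay open.

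The jasmonate and wound list was lowest in replicate 1, where the Bowman-Birk locus is among those far lower. Without these loci the list's SD fell from 0.39 to 0.19 and its percentile from 99.99 to 97.31, with an adjusted share of 0.054. With 1 more gene left out the SD went as low as 0.147, under the 0.169 that 95% of random lists stayed below. Replicate 1 moved from -0.55 to -0.20 without the Bowman-Birk locus, against -0.13 in replicate 2, so much of its low mean rested on that locus. Whether the other 12 genes exceed random lists stays uncertain, although the percentile by itself passed the bound set beforehand. No biological explanation was tested.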

How the results depend on the processing

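Alternatives named here as added were chosen after seeing the data. No paired analysis was possible because there is only 1 group. The number of probes detected (32384) stayed within 1.5 times under each alternative, from 32444 with flagged spots left in to 35613 on any array, and from 32468 to 32809 with 1 replicate left out. The replicate spread, a median SD of 0.166, was 0.217 with no detection filter. It was 0.0751 between spots within an array for 163 probes, whose single spots had 0.292 between arrays. Added, it was 0.082 and 0.122 in pairs from scan 1 and scan 2, an SD of 2 arrays that cannot be set against one of 4. Leaving out 1 replicate gave 0.131 to 0.172. The 3600 differing genes became 2322 with scan as a term, fitted within scans, and, added, 1062 with pairs that share no 15 bases, of 3377 tested; leaving out 1 replicate gave 1486 (without replicate 4) to 3200. In the full fit 69.5% of pairs that share 15 bases and 43.9% of the others differed; the cause was not tested. The 11 lists above the 95th percentile became 7 with the brighter probes alone (the cause was not tested), and 8 to 13 with 1 replicate left out. The 11 lists whose detected share differed became 7 under the positive-and-significant call and 7 when any array sufficed, where more of all other loci are detected, and 10 to 12 with 1 replicate left out. Cyclic loess cut the deviation of cytosolic ribosomal genes in replicate 4 from 0.30 to 0.15 and put core histones at the 66.3rd percentile. Normexp raised the median gene by 0.11 in replicate 1 and 0.12 in replicate 4. Over single lists, 341 alternatives kept the side of the threshold, 16 lost it and 11 gained it. Of the levels of single genes, 760 stayed within 1 SD and 19 moved further, under normexp, no detection filter or brighter probes alone; with no detection filter other probes enter, and Os03g0563300 stood at -3.29. Of the ranges of single genes, 294 stayed on their side of the threshold, and 2 did not (Os01g0781000 without replicate 1 and Os02g0538700 with no detection filter). Leaving out saturated probes moved nothing, since none were saturated. Dim probes limited precision: the median SD was 0.28 in the dimmest 8096 probes and 0.14 in the brightest 8096.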

Other observations

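Of the 102 probes at least 8-fold lower in replicate 1, 6 had a resistance-type description, against 206 of 32425 testable probes. This difference was not tested, and these loci were picked after their values were seen. All 6 lay in the runs from Os01g0780900 to Os01g0782100 and from Os11g0224900 to Os11g0226800, so they are not separate events. The longest run took in all 7 loci on the array from Os01g0780900 to Os01g0782100 on chromosome 1, among them VPS28 and the rust resistance-like genes Os01g0781100 and Os01g0781200. On chromosome 11, 4 of the 9 array loci from Os11g0224900 to Os11g0226800 were at least 8-fold lower and not above background in replicate 1, so the size of the difference was not measured. Further groups lay on chromosome 1 from Os01g0144100 to Os01g0148400 (6 of 22 array loci) and on chromosome 4 from Os04g0121900 to Os04g0127200 (4 of 11). Of 23 such loci with several testable probes, all probes were at least 8-fold lower in 14 and at least 2-fold lower in 19. Each locus was picked for at least 1 probe 8-fold lower, and probes of a locus can share sequence, as those of Os01g0781000 do. The other probes are therefore not independent support.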
